A study of Mus musculus with 4 samples.

How the data were processed

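Total RNA of 4 RAW264.7 cultures was measured on 4 Agilent mouse expression arrays, 1 array per culture, labelled in 1 colour with Cy3, per the labels. RAW264.7 is an established mouse macrophage-like line. Per the labels' protocols, the cells carried a stably integrated expression vector for an artificial microRNA, either a scramble control or one directed against Linc-AAM, a long intergenic non-coding RNA, and were selected as bulk cultures. They were then kept for 4 h in DMEM medium without or with 50 µg/mL AEPS, a polysaccharide prepared from Actinidia eriantha roots. The labels thus give 4 groups of 1 array each. The replicate number in the labels only names the array. Nothing in the labels says that any culture was repeated.

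The deposited scanner files hold a spot intensity on a linear scale, read with Agilent Feature Extraction, the tool named in the submitters' processing notes, in version 10.7.1.1, per the file headers. Per the file headers, the processed intensity was background-subtracted and detrended within each array, dim spots received a surrogate value, and nothing was scaled between arrays. The same files give the mean intensity of each spot, the median of its local background, and marks for spots that are well above background, saturated or outliers, per the file headers. The probe coordinates used here are those the scanner files carry for mm9, and an aligner or annotation release is not given in the sources used here. All 4 arrays lay on 1 slide and shared 1 scan, so slide and scan do not differ between groups. The deposited series value table holds log2 values made by the authors, whose processing is not given in the sources used here. From its values, its 4 columns hold the same sorted values within 0.0023, as quantile normalization leaves them, each column has a median of 4.7, and the values are not centred per gene. Its scale was taken as log2 from the match with the scanner values.

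For the main values, log2 of the processed intensity was reduced by each array's 75th percentile over non-control spots. Control spots and spots marked as non-uniform or population outliers were left out (164, 200, 171 and 231 outlier spots on the arrays of scramble in DMEM, scramble under AEPS, knockdown in DMEM and knockdown under AEPS), and the spots of a probe were averaged. A gene with several probes took the probe with the highest mean signal over the 4 arrays. Among 3393 genes with 2 or more measured probes, the median range between probes was 0.14 to 0.207 log2 units over the pairwise comparisons, and 0 genes had probes that differed at least 2-fold in opposite directions. Probe names were updated through an NCBI RefSeq gene table, by accession for 26582 probes, by symbol for 2602 and by synonym for 492, and the name of the design was kept for 26005. This gave 36086 genes or names, of which 23947 were well above background on 1 or more arrays, 22341 on 2 or more and 20339 on all 4.

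Arrays within a line or a treatment were compared by size, because a group holds 1 array. A gene was called higher or lower when both arrays were well above background and differed at least 2-fold, which is 1 on the log2 scale. A gene well above background on 1 of the 2 arrays was called when its bound reached 2-fold. The bound sets the bright array against the higher of the dim probe's own value and the lowest signal well above background on the dim array, and it is written as "at least". The difference in response is the AEPS effect on the arrays labelled knockdown minus that on the arrays labelled scramble. It has 0 residual degrees of freedom with an interaction in the model and therefore no test. An additive model of line and treatment was fitted with limma (lmFit and eBayes) to the 22341 genes well above background on 2 or more arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Its residual is the line-by-treatment difference, with 1 degree of freedom, and the prior added 2.82 degrees of freedom with a prior SD of 0.132. A gene whose response differed between the lines was therefore less easily called. The p-values measure only the spread between these arrays.

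Fixed before the data were examined were 29 gene lists, the designs and most of the other settings tried. For each list, the median difference was set among 10000 random lists of the same size, matched on mean signal in 20 bins, and its percentile is a description of these arrays and not a test. Counts of list members called by limma are given over all genes tested and adjusted over the list alone. The genes named in the text follow a rule fixed at the same time. Among genes with an official-style symbol, for each pairwise comparison it takes the 8 largest increases and 8 largest decreases that were also at least 2-fold in the same direction with the normexp background and with quantile normalization, the 4 largest bounds each way, and up to 4 members per list. For the difference in response it takes the 8 largest and 8 smallest under the same condition, and for each limma effect the 10 smallest adjusted p-values. Hnrnpl, Tlr2, Tlr4, Tnf, Il6, Il1b and Nos2 were always named. Any other gene is said to have been chosen after its values were seen.

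The steps were tested on simulated data built from these arrays. For the AEPS effect over both lines, with 22341 genes and 200 of them changed, limma recovered 0 of 100 genes changed by 1 on the log2 scale and 66 of 100 changed by 2, with 3 false calls and 0 calls for the line. On the real arrays 33.9% of genes had an unadjusted limma p under 0.05 for AEPS, a larger share than was changed here. The adjustment depends on that share, so these recoveries do not carry over to the real fit. For AEPS against DMEM in the scramble line, with 20339 genes, the rule by size called 99.0% of genes changed by 1.5 and 3 unchanged genes. The noise in that simulation was normal with the same SD for all genes, 0.185, and all genes were set well above background. Without replicates the real noise of single genes is not known, so the 3 calls do not give the rate of false calls on these arrays. For the share of smaller responses, responses built 0.8 times as large gave 88.4% of genes smaller. For the gene lists, 5.5% of lists with no shift lay outside the central 95% of random lists. Those lists were drawn at random from values shuffled over genes, whereas members of the real lists can move together. The 5.5% therefore checks the computation only and not the percentiles of the real lists.

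The other settings fixed at that time were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes well above background on all 4 arrays, the value table in place of the scanner files, the mean of a gene's probes, outlier spots kept, dim values floored at the lowest signal well above background, other filters on dim probes, a 3-fold size, and limma with an intensity trend. After seeing the data, the columns of the value table were matched to arrays by rank for that setting. Also added after seeing the data were the same table taken with its columns as labelled, lists of members measured on the compared arrays, and the share of smaller responses without the interferon-stimulated genes. For chromosome positions, genes well above background on all 4 arrays were grouped in 254 windows of 10 Mb with 20 or more genes, and window medians were compared with 10000 shuffles of the gene positions. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. No array was left out.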

Results

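Expression was measured in RAW264.7, a mouse macrophage-like cell line, on Agilent arrays that read many genes with short probes. The 4 arrays formed 4 groups of 1, namely cells with a scramble vector and cells with a Linc-AAM knockdown vector, each kept for 4 h in DMEM medium or with 50 µg/mL AEPS, a plant polysaccharide. The design asks what AEPS does to gene expression in these macrophages and whether cells with a vector against Linc-AAM, a long intergenic non-coding RNA, respond differently. Each array held 62976 spots, of which 59305 were not controls, for 55681 distinct probes. Spots well above background made up 58.0% on the array of scramble in DMEM, 56.1% for scramble under AEPS, 53.4% for knockdown in DMEM and 54.8% for knockdown under AEPS. The 75th percentiles of the processed intensity were 587.7, 509.7, 439.1 and 448.3 in the same order, and 0 spots were saturated. Probes printed 10 times on an array had a median SD between spots of 0.036 to 0.046 on the log2 scale, which is the error within an array. No group had a replicate, so pairwise differences have no replicate check, and the number of arrays limits their precision.

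The targeted RNA was not used to check the labels. A search by name found Linc-AAM in 0 gene names of the array design. Probes that may read it under another name were not searched for, and its level was not analysed here. The scanner files and the value table disagree on which line is which. The table's column labelled scramble in DMEM ranked the probes like the scanner file labelled knockdown in DMEM (Spearman rho across probes 0.99993) and less like its own scanner file (0.96874). Over the 4 columns, rho was at least 0.99993 with the other line's array of the same treatment and at most 0.96886 with the own array, while DMEM and AEPS stood in the same place in both. Probes are not independent replicates, and no value examined here shows which source names the lines correctly. Lines are therefore named as on the scanner files, as "the array labelled knockdown" or "labelled scramble", and under the value table's labels each difference between the lines takes the opposite sign. The AEPS effect over both lines does not depend on these labels. In the mm9 coordinates of the array, 1 probe each read Il1b (chromosome 2, 129190347 to 129190406), Il6 (chromosome 5, 30346367 to 30346426), Tnf (chromosome 17, 35336795 to 35336854), Nos2 (chromosome 11, 78773567 to 78773626), Tlr2 (chromosome 3, 83640344 to 83640403), Tlr4 (chromosome 4, 66503470 to 66503529), Hnrnpl (chromosome 7, 29605608 to 29605667) and Igf2bp1 (chromosome 11, 95824526 to 95824585).

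Across both lines, AEPS raised the genes of inflammation, with the largest effects among cytokines and chemokines. Of 17 tested proinflammatory cytokine genes, 15 rose and 0 fell by limma (16 and 0 adjusted over the list alone). Il1b rose by 11.78 ± 0.76 on the log2 scale (SE; limma adjusted p = 0.00946), and Il6, whose product drives the acute phase response, rose by 8.22 ± 0.61 (limma adjusted p = 0.0113) from a level not well above background in DMEM. Tnf rose by 4.92 ± 0.44 (limma adjusted p = 0.0143). Of 16 chemokine genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), among them Ccl5 by 8.86, Cxcl2, which attracts neutrophils, by 9.27, and Ccl22 by 6.70. Interferon-stimulated genes, which encode antiviral proteins, rose in 29 of 35 cases with 0 lower (35 and 0 adjusted over the list alone), including Isg15 by 6.32 ± 0.12 (limma adjusted p = 0.00605), Ifit1 by 6.98 and Rsad2 by 6.42.

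Genes on the list of NF-kB signalling and its feedback rose in 19 of 23 cases with 0 lower (22 and 0 adjusted over the list alone). The feedback inhibitor Tnfaip3 was up by 4.58, and Socs3, also on that list, by 4.95. Immediate early genes rose in 13 of 24 cases and fell in 1 (16 and 3 adjusted over the list alone), with Ier3 up by 3.80 and Nr4a2 down by a log2 difference of -0.75. Among 27 pattern recognition receptors and adaptors, 10 rose and 3 fell (13 and 3 adjusted over the list alone). Tlr2 rose by 1.57 ± 0.11 (limma adjusted p = 0.011), and Nod2 and Nlrp3 rose by 4.09 and 3.04, whereas Tlr4, the receptor for bacterial lipopolysaccharide, fell by 1.68 (limma adjusted p = 0.0433). Of 16 enzymes of nitric oxide, prostaglandin and itaconate synthesis 8 rose and 0 fell (9 and 1 adjusted over the list alone), with Nos2 up by 2.32, Ptgs2 by 4.31 and Acod1, which makes itaconate, by 6.24. Antigen presentation and costimulation genes rose in 7 of 20 cases with 0 lower (13 and 0 adjusted over the list alone), with Cd40 up by 6.13 and Cd274 by 4.33. Alternative activation genes rose in 8 of 15 cases with 0 lower (8 and 1 adjusted over the list alone), with Il10, an anti-inflammatory cytokine, up by 3.58 and Irf4 by 5.22.

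Macrophage identity genes rose in 4 of 26 cases and fell in 2 (7 and 2 adjusted over the list alone), with the integrin gene Itgax up by 2.34. Of 10 osteoclast genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), with Mmp9, a matrix protease gene, up by 4.86. Lysosome and phagocytosis genes rose in 2 of 25 cases and fell in 3 (4 and 5 adjusted over the list alone), with Axl up by 2.64 and the lysosomal regulator Tfeb at -1.93. Of 26 cholesterol and lipid synthesis genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Dhcr7 at -1.47, and of 9 cholesterol efflux genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), namely the transporter genes Abca1 (3.15) and Abcg1 (-1.04).

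Genes of proliferation went the other way. Of 32 cell cycle genes 0 rose and 19 fell (0 and 30 adjusted over the list alone), including the replication licensing gene Cdc6, which fell by 2.73, and Ccne1, which fell by 2.11. Of 11 replication-dependent histone genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), with H1f5 down by a log2 difference of -0.82. Genes of p53 targets and apoptosis rose in 11 of 22 cases and fell in 3 (12 and 4 adjusted over the list alone), with the death receptor Fas up by 5.43 and Gadd45b by 4.03. Glycolysis and hypoxia genes rose in 8 of 20 cases with 0 lower (9 and 1 adjusted over the list alone), such as Slc2a1, the glucose transporter, by 1.49 and Hk2 by 1.35. Outside the lists, the smallest adjusted p (0.00605, limma) was shared by Col5a3, up by 10.42, Tslp by 5.95, Lad1 by 5.43, Shbg by 5.42 and Cltrn by 5.39, and by Bhmt2, which fell by 5.61. For genes not well above background in 1 of the treatments, such as Il6, Col5a3 and Bhmt2, the fitted size rests on values near the background. In all, limma called 1653 genes higher and 1629 lower among 22341, of which 1068 and 820 changed at least 2-fold. The error in this fit is the difference in response between the lines, with 1 residual degree of freedom, and each treatment has 2 arrays, 1 per line. Without a filter on dim genes limma called 271 higher and 32 lower, and with an intensity trend 3622 and 3076.

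**Figure D1:**
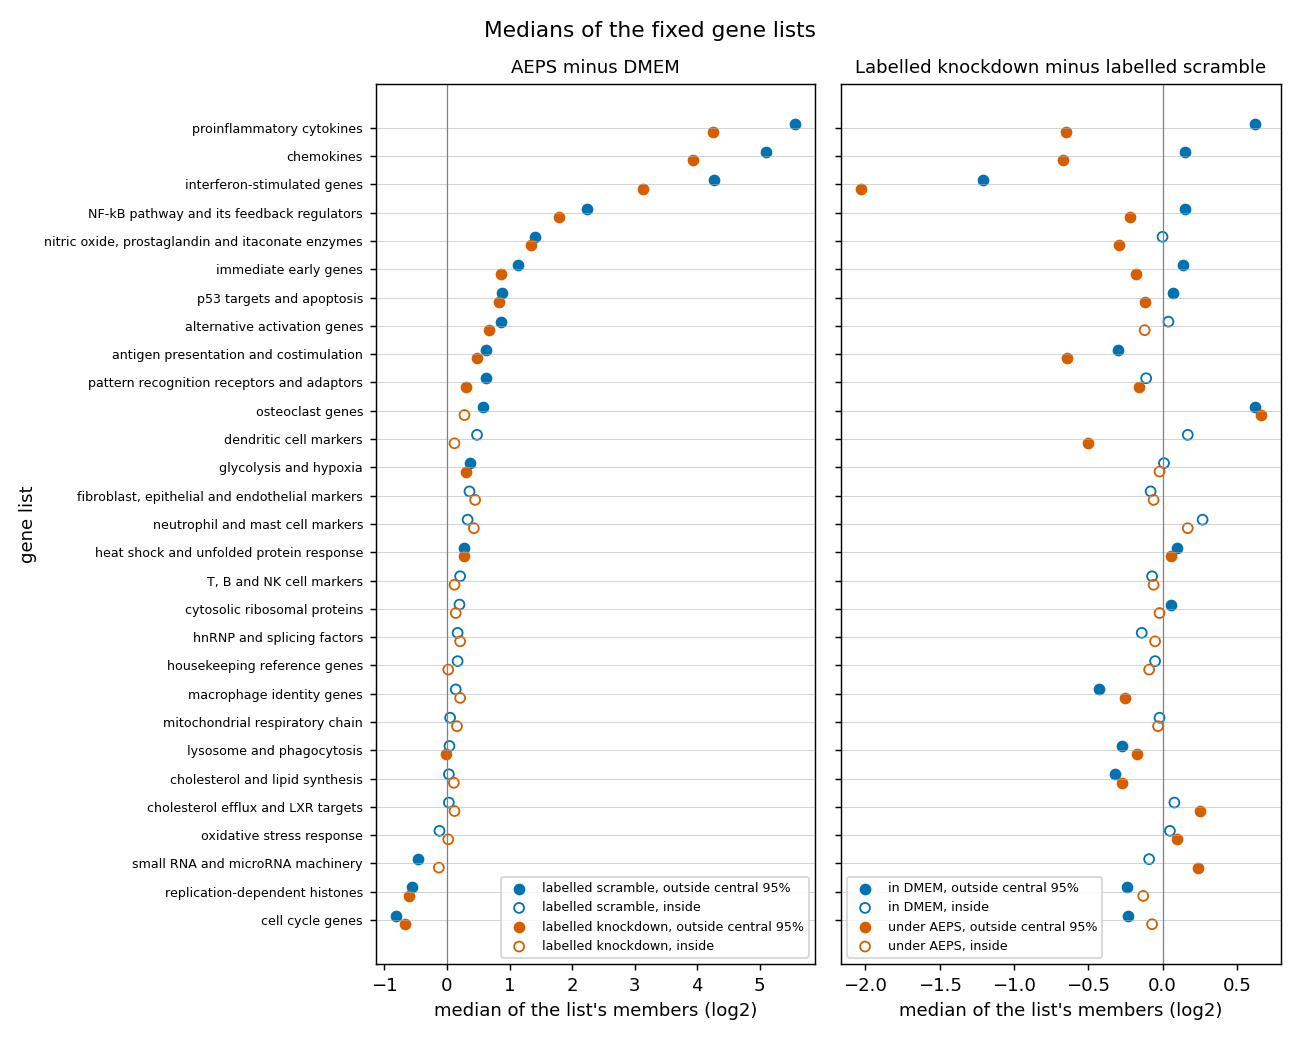
Median log2 difference of the members of each of the 29 fixed gene lists, for AEPS minus DMEM in each line (left) and for labelled knockdown minus labelled scramble in each medium (right), with filled points outside the central 95% of 10000 matched random lists. Cytokines reach 5.57 and 4.26 on the left and cell cycle genes -0.82 and -0.67, while on the right interferon-stimulated genes lie at -1.21 and -2.03 (the cytokine median of 0.62 in DMEM includes members below background on both arrays, and is 0.43 without them).

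The arrays labelled scramble ask what AEPS does in control cells if the scanner files name the lines correctly, and under the value table's labels their values belong to the knockdown line. On them, Il1b was 9682-fold higher under AEPS (13.24 on the log2 scale), Cxcl2 1158-fold and Ccl5 717-fold higher. Genes not well above background in DMEM included Il1a, at least 10.23 higher on the log2 scale, the granulocyte growth factor gene Csf3, at least 9.17, Hdc, which makes histamine, at least 9.16, and Il6, at least 148-fold higher. All 35 interferon-stimulated genes were called higher, with a list median of 4.27. Saa3, an acute phase gene, was 7.80 higher and the prostaglandin receptor gene Ptger2 7.24 higher. Lower under AEPS were Cytip (-4.13), Klhl6 (-4.04), Cbx2 (-3.68), the pore-forming gene Gsdme (-3.55), Angptl2 (-3.47) and the cell cycle activator E2f2 (-3.52), and Lrrc17 had a bound of -4.48. In total 1566 genes were called higher and 1226 lower (974 and 876 for the column pair that the value table labels scramble), 1190 and 1072 of them measured on both arrays, and 1000 and 733 with the normexp background. Quantile normalization shifted the median of all genes from 0.063 to -0.048 and gave 1398 higher and 1359 lower.

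The arrays labelled knockdown ask the same of cells with the Linc-AAM vector, and under the value table's labels their values are those of the scramble line. On them, cytokine and chemokine genes again had the highest list medians (4.26 and 3.93). Il1b was 1278-fold higher under AEPS (10.32 on the log2 scale), Cxcl2 327-fold, Ccl5 301-fold, Isg15 75.1-fold and Nos2 6.65-fold higher, and Flrt3 was 7.22 and Acod1 5.76 higher on the log2 scale. Bounds were at least 9.18 for Il1a, 8.59 for Col5a3, 8.08 for Csf3 and 7.22 for Hdc. Of the interferon-stimulated genes 32 of 35 were called higher, with a list median of 3.14. Angptl2 (-3.38), Klhl6 (-3.13), Arhgap27 (-3.08), St6gal1 (-2.80) and Gsdme (-2.85) were lower. In total 1034 genes were called higher and 778 lower (1424 and 1341 for the column pair that the value table labels knockdown, and 703 and 385 with the normexp background). The lists of the 2 lines overlapped, from arrays that share no sample. Among 21898 genes, 875 were higher in both where independent lists would share 63.4, 572 were lower in both where 37.2 would be shared, and 7 and 0 were called in opposite directions. Across 20339 genes, which are not independent replicates, the responses correlated with Pearson's r of 0.882 and Spearman's rho of 0.738.

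The responses differed in size between the lines. Among genes well above background on all 4 arrays, the smallest values of the response on the arrays labelled knockdown minus that on the arrays labelled scramble belonged to Rsph4a (-3.49), the myeloid receptor gene Cd300e (-3.32), the cytokine genes Tnfsf15 (-3.03), Osm (-3.00) and Il1b (-2.92), and the interferon-stimulated genes Ifit2 (-2.94), Gbp5 (-2.85) and Tgtp2 (-2.70). Tnf differed by -1.66. Such a value can come from the level in DMEM as well as from the level under AEPS. Cd300e, Osm, Il1b and Tnf were already higher in DMEM on the array labelled knockdown than on that labelled scramble. The largest positive values belonged to Hdac9 (2.37), Cytip (1.87), Ptchd1 (1.59) and Zic2 (1.51), and Tlr4 had 1.07 and Nos2 0.83. Over list members well above background on 1 or more arrays, the medians were -1.01 for cytokines, -1.12 for interferon-stimulated genes, -0.55 for chemokines and -0.44 for NF-kB genes. Each lay at percentile 0 of random lists, and cell cycle genes had 0.18, at percentile 99.9. Over members well above background on all 4 arrays, cytokines had -1.12, interferon-stimulated genes -1.05 and chemokines -0.53. The random lists were matched on mean signal and not on the size of the AEPS response. Since most large responses were smaller on the arrays labelled knockdown, these percentiles do not show an effect particular to a list. A value of 1 or more in size was found for 107 genes upward and 331 downward of 20339 (300 and 112 with the value table's labels). The counts were 26 and 191 with the normexp background and 304 and 611 with genes well above background on 2 or more arrays. Of 1659 genes with a mean AEPS effect of at least 2-fold, 1402 had the smaller response on the arrays labelled knockdown, which is 84.5% (exact binomial 95% interval 82.7 to 86.2, over genes, which are not independent), and 16.6% with the value table's labels. Genes with a higher level under AEPS had median responses of 2.02 on the arrays labelled scramble and 1.56 on those labelled knockdown, and genes with a lower level had -1.55 and -1.20. The difference in response had no test.

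**Figure D2:**
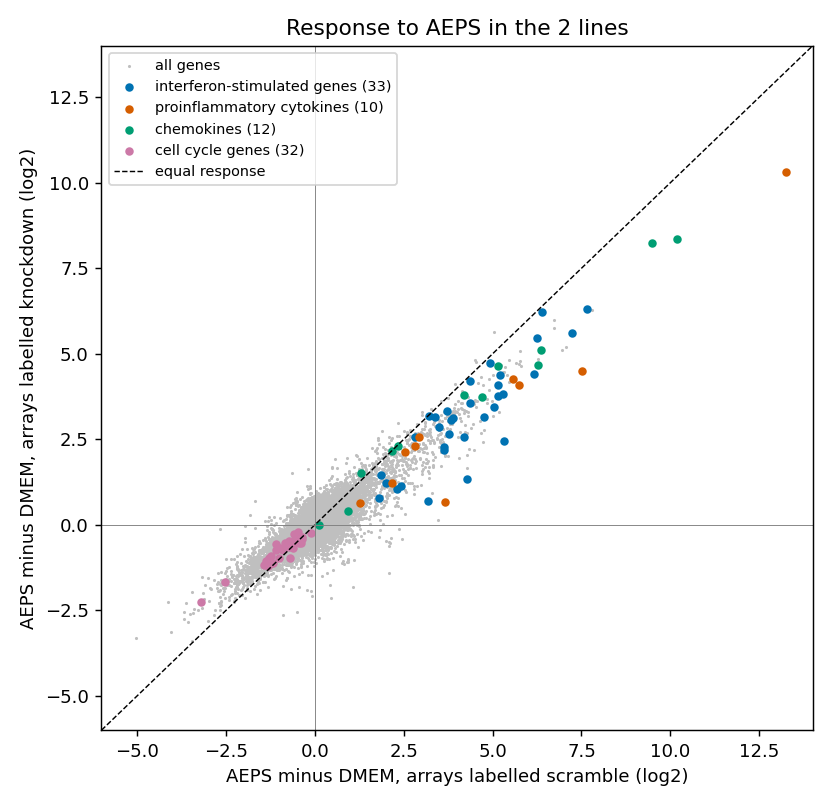
AEPS minus DMEM on the arrays labelled knockdown (y axis, log2) against the same on the arrays labelled scramble (x axis, log2) for 20339 genes well above background on all 4 arrays, with members of 4 lists in colour and a dashed line of equal response. The slope of the major axis is 0.788, and Il1b lies at 13.24 and 10.32.

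In DMEM, where the 2 lines were compared without AEPS, the array labelled knockdown had more Slc9b2 (18.8-fold), Pvt1, a long non-coding RNA gene next to Myc (14.2-fold), Zfp462 (4.54 on the log2 scale), Prkar2b (4.12), Timp1 (3.92), Cd300e (3.85) and Axl, a receptor in the uptake of dying cells (3.54). Maged1 and Wnt10b, not well above background on the array labelled scramble, had bounds of at least 4.94 and 4.20. Lower on the array labelled knockdown were Sly (-6.30), Slc9a7 (-4.62), Zfp979 (-3.65), Peg12 (-3.48) and Ppfia4 (-3.18), and bounds were -6.45 for the RNA-binding gene Igf2bp1, -5.54 for Fam149a, -5.39 for the Btg3 probe and -4.75 for Hoxb13. Whether the only Btg3 probe reads Btg3 or another copy was not tested, so each Btg3 value is that of a probe of uncertain identity. Interferon-stimulated genes were lower, 18 of 35 called and none higher, with a median of -1.21 and, as examples, Oasl2 at -2.36 and Ifit1 at -2.03. Macrophage identity genes had a median of -0.43, cholesterol and lipid synthesis genes -0.32 and antigen presentation genes -0.30, all at or below percentile 0.01 of random lists. Osteoclast genes had 0.62 (percentile 100), with the acid phosphatase gene Acp5 at 2.72 and Ctsk at 1.56. Il1b was 2.56 higher, Osm 2.35 and Tnf 0.82. In total 537 genes were called higher and 346 lower (370 and 489 with the value table's labels, 191 and 142 with the normexp background), and 345 and 241 of them were measured on both arrays.

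Under AEPS, which asks how the lines differ once stimulated, interferon-stimulated genes were lower on the array labelled knockdown in 33 of 35 cases, with a median of -2.03 at percentile 0. Mx1 (-4.92), Oasl2 (-3.94), Ifit2 (-3.80), Rsad2 (-3.64), Ifit3 (-3.56) and Ifit1 (-3.38) led them. Outside the list, Marcks, which binds the cell membrane, had -4.43 and Ifi209 -4.35. Cytokines had a median of -0.65, chemokines -0.67 and antigen presentation genes -0.64, with Il6 at -1.71, Tnf at -0.84, Cxcl10 at -2.08 and Tap1, a peptide transporter gene, at -2.48. Nos2 was 1.17 higher, and osteoclast genes had a median of 0.66. Several genes of the comparison in DMEM stood out again, such as Slc9b2 (4.43), Zfp462 (4.20), Pvt1 (3.85), the uncertain Btg3 probe (-6.82), Sly (-6.17) and, with a bound, Igf2bp1 (-6.82). In total 418 genes were called higher and 608 lower (611 and 427 with the value table's labels, 151 and 335 with the normexp background). Of 21901 genes, 174 were called higher and 180 lower in both media, where independent lists would share 6.7 and 6.4, and 7 and 1 were called in opposite directions, from arrays that share no sample.

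**Figure D3:**
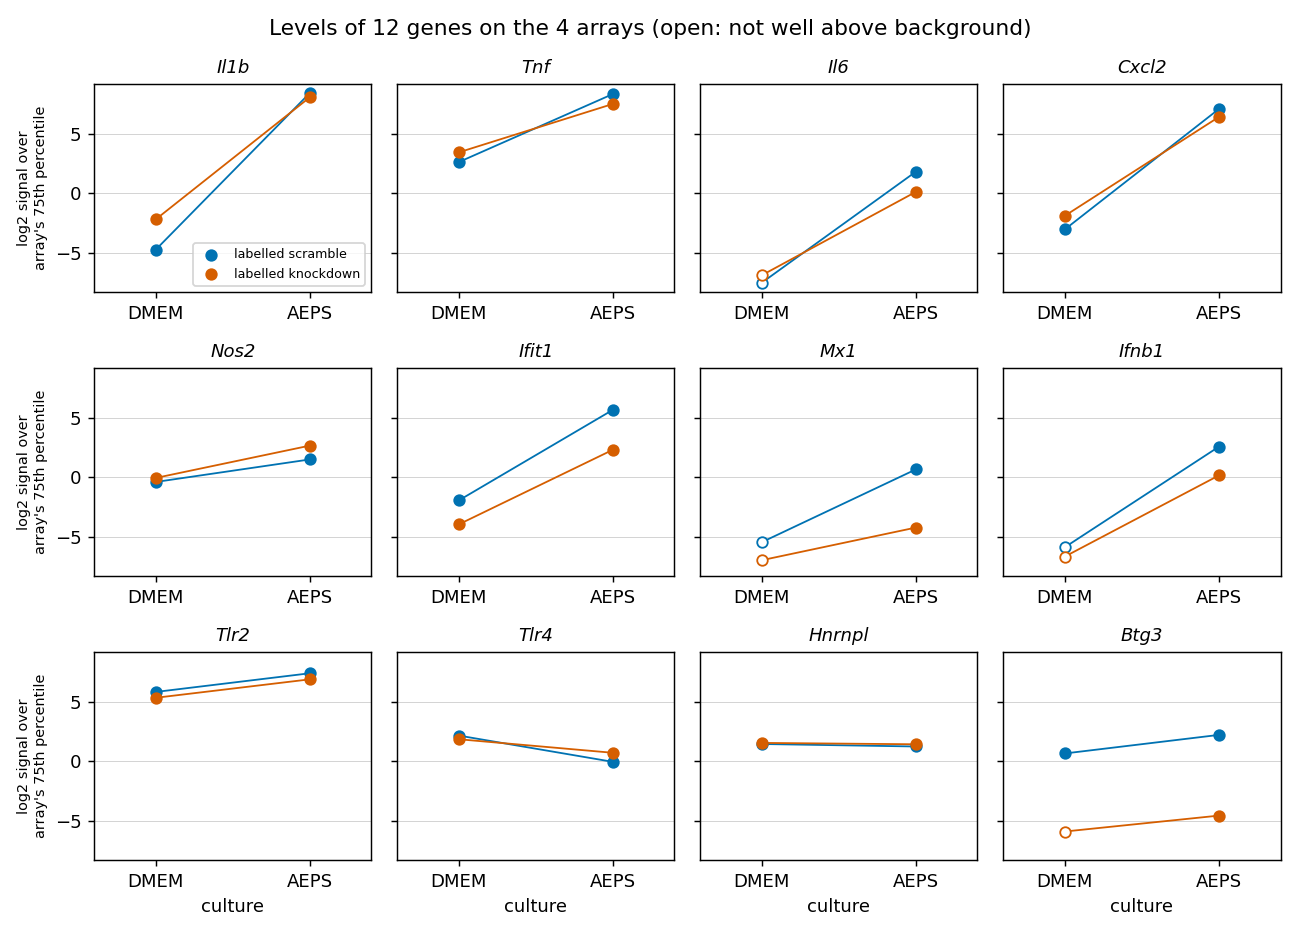
Level of 12 genes on each of the 4 arrays (y axis, log2 signal relative to the array's 75th percentile) in DMEM and under AEPS, in blue for the arrays labelled scramble and in orange for those labelled knockdown, with open points not well above background. Il1b and Tnf start higher and end lower on the arrays labelled knockdown, Ifit1 is lower in both media, and the Btg3 probe, of uncertain identity, is lower in both media, with a bound of -5.39 in DMEM (Ifnb1 was chosen after its values were seen).

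Over both media, limma called 89 genes higher and 76 lower on the arrays labelled knockdown, all of them at least 2-fold (66 and 76 with the value table's labels). The signal of the only Btg3 probe fell (limma adjusted p = 0.0145), with a bound of -5.39 in DMEM, where it was not well above background on the array labelled knockdown, and -6.82 under AEPS. That probe is placed on chromosome 17 from 50839065 to 50839124 in the array's mm9 coordinates, and the copy it reads is uncertain. Sly, a gene with many near-identical copies on the Y chromosome, fell by 6.23 (limma adjusted p = 0.0145), but only 2 of its 5 probes were well above background on any array, so the copy measured is uncertain. Igf2bp1 fell by 8.15 (limma adjusted p = 0.0256), a size that rests on levels not well above background on the arrays labelled knockdown, and the smallest adjusted p-values included Agap2 and Lin28b, which fell to levels not well above background on 1 or both arrays labelled knockdown (bounds of -3.43 and -3.94 in DMEM), and Slc9b2 and Pvt1, which rose by 4.33 and 3.84 (limma adjusted p = 0.0197 each). Of 35 interferon-stimulated genes 0 were higher and 2 lower by limma (0 and 32 adjusted over the list alone), namely Ifih1, a sensor of double-stranded RNA (-1.76), and Dhx58 (-1.73), both chosen after their values were seen. In other lists, the osteoclast protease gene Ctsk rose (1.56 in DMEM and 1.43 under AEPS, 1 higher and 0 lower of 10, 6 and 0 adjusted over the list alone), Mpeg1 fell by 1.70 (0 and 1 of 26 macrophage identity genes, 0 and 7 adjusted over the list alone), Atf3 was at -1.80 (0 and 1 of 24 immediate early genes, 1 and 3 adjusted over the list alone), Ptgs1 rose by 2.25 (1 and 0 of 16, 1 and 3 adjusted over the list alone) and Gas6 rose by 1.44 (1 and 0 of 25 lysosome and phagocytosis genes, 2 and 3 adjusted over the list alone). Hnrnpl, which encodes an RNA-binding splicing regulator, differed by 0.14 ± 0.12 (limma adjusted p = 0.641). The 2 arrays of a line come from the same stable culture, so this p-value does not measure the spread between independent knockdown cultures. Without a filter on dim genes limma called 0 and 0 genes (3043 at an unadjusted p under 0.05), and with the 75th percentile taken over measured probes it called 41 and 31. Other settings gave more calls, with 418 and 316 for the normexp background and 581 and 707 for an intensity trend. With genes well above background on all 4 arrays limma called 187 and 150.

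Genes were also set along the chromosomes in mm9 coordinates, a view chosen after the data were seen. On chromosome 9, the 116 genes in the windows from 0 to 10 and from 20 to 30 Mb, with probes starting between 3003722 and 27155814, had a median difference of 0.33 in DMEM (1.26-fold) and 0.38 under AEPS (1.3-fold) on the arrays labelled knockdown. In each pair 86.2% of them were higher. The window between them, from 10 to 20 Mb, had 0.22 and 0.24 and did not pass in the DMEM pair alone (familywise p = 0.0527 by shuffling gene positions, a permutation test) but did over both pairs (0.0027). Windows that passed in the DMEM pair with lower medians were those from 70 to 80 Mb of chromosome 9 (-0.36 in DMEM and -0.15 under AEPS), 140 to 150 Mb of chromosome 1 (-0.35 and -0.12), 10 to 20 Mb of chromosome 3 (-0.31 and -0.23) and 20 to 30 Mb of chromosome 4 (-0.25 and -0.14). The other 894 genes of chromosome 9 had a median of 0.01 over both pairs. They include the windows from 10 to 20 Mb (0.23 over both pairs) and from 70 to 80 Mb (-0.25), so 0.01 does not hold for each part. The single-gene differences in this block were mostly under 2-fold, with 4 genes called higher in DMEM and 3 under AEPS.

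**Figure D4:**
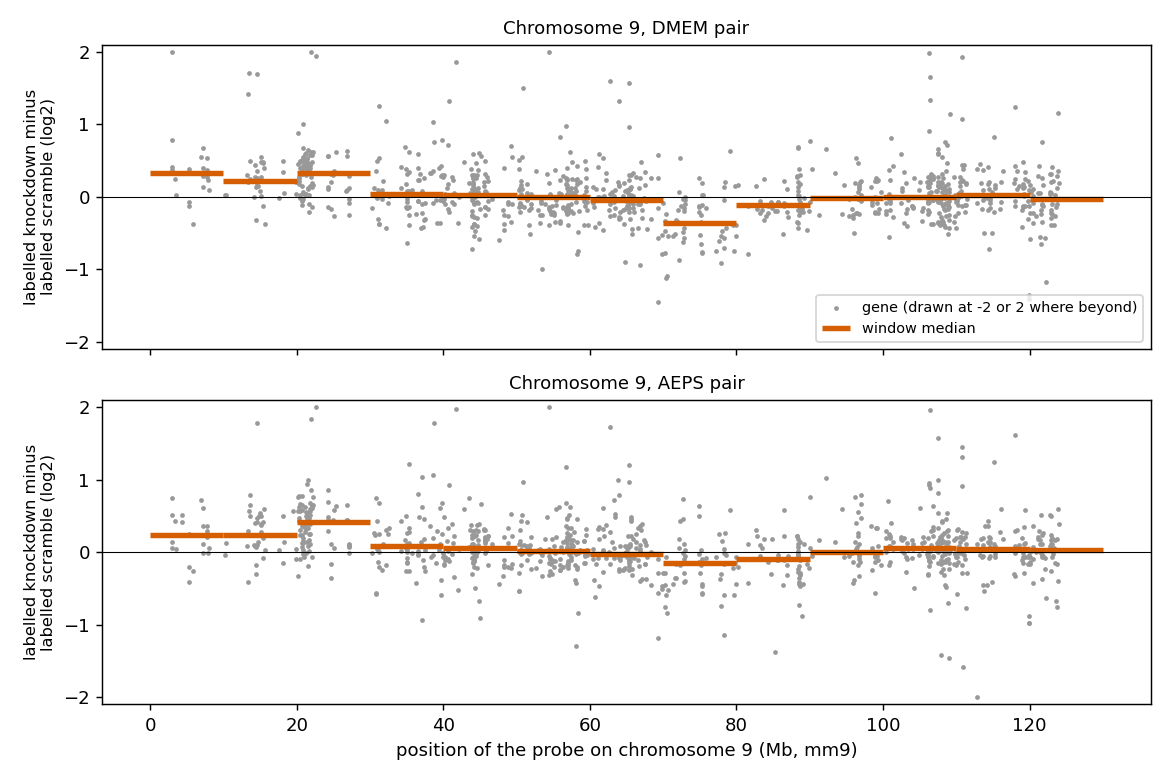
Difference between labelled knockdown and labelled scramble (y axis, log2, with points beyond 2 drawn at 2 and those below -2 at -2) of single genes along chromosome 9 (x axis, position in Mb, mm9), for the pair in DMEM and the pair under AEPS, with orange lines for the medians of windows of 10 Mb. The windows from 0 to 10 and from 20 to 30 Mb lie above 0 in both pairs, at 0.33 and 0.33 in DMEM and 0.23 and 0.41 under AEPS.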

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

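The tests of spike-in slope, scaling and exposure were chosen only after the smaller responses on the arrays labelled knockdown were seen, though the scalings themselves had been fixed earlier, and the share without interferon-stimulated genes was added after that list's difference was seen but before the share itself was. Cytokine genes measured on a compared array had a median of 0.43 in DMEM (11 genes, 7 above 0 and 4 below) and -0.65 under AEPS (17 genes, 1 above and 16 below) on the arrays labelled knockdown relative to scramble, so the medians had opposite signs over different members. Chemokine genes had 0.10 (12 genes, 7 above and 5 below) and -0.67 (17 genes, 2 above and 15 below). NF-kB genes had 0.15 and -0.22 over 23 genes in each medium, of which 14 and 3 lay above 0. Immediate early genes had 0.10 over 23 genes and -0.18 over 24, of which 13 and 11 lay above 0. Hdac9, a histone deacetylase gene, lay at -1.36 in DMEM and 1.01 under AEPS. Rsph4a, a gene of motile cilia, lay at 1.75 and -1.75, and its response to AEPS was 2.1 on the arrays labelled scramble and -1.39 on those labelled knockdown. In each case the difference was not tested, because each group has 1 array, and all signs turn under the value table's line labels.

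Most genes with a large AEPS effect had the smaller response on the arrays labelled knockdown. A flatter signal response of those arrays is argued against by the spike-in probes, whose lowest slope there lay 0.046 above the highest slope on the arrays labelled scramble. Scaling between arrays left the share of smaller responses at 81.9% or higher over both 75th percentile scalings, quantile normalization and the value table matched by rank, in genes of both directions. Without the interferon-stimulated genes the share was 84.2%, but 1626 of the 1659 genes remained. Leaving out so few genes could hardly move the share, so this value does not decide what part interferon signalling had. A weaker exposure of that culture to AEPS cannot be told apart from an effect of the vector, since there was 1 array per line and treatment. It would not account for differences already present in DMEM, where 18 of 35 interferon-stimulated genes were called lower with a list median of -1.21. Those differences do not show what made the responses to AEPS smaller. An effect of the vector against Linc-AAM stays open and was not tested, since the level of Linc-AAM was not analysed here and the value table's line labels turn the direction.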

How the results depend on the processing

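The value table with its columns as labelled, the lists limited to measured members and the share without interferon-stimulated genes were chosen only after the results were seen. Of 147 alternative values of gene counts and of the share of smaller responses, 94 stayed within 1.5 times the reported count or within the interval of the share, 52 moved and 1 reversed. Counts were compared by their size only, so a count could not be scored as reversed. With the value table's columns as labelled, 10 of 15 values stayed, although each difference between the lines takes the opposite sign there. List medians kept their place inside, above or below the central 95% of random lists in 1111 of 1160 values. Of the rest, 30 were weaker, 19 stronger and 0 reversed. Named genes kept their call, or stayed uncalled, in 4084 of 4318 values, with 222 weaker, 6 stronger and 6 reversed. The sign was not compared for medians inside the central 95% or for genes that stayed uncalled. With the value table's columns as labelled, lists were not run and named genes only where always named (49 values). These totals therefore leave out most sign changes that the disputed line labels would give. No paired analysis by replicate number was possible because each group has 1 array and the replicate number only names it. The additive limma model already compares the treatments within the lines, and without any 1 array the additive model has 0 residual degrees of freedom. Signal over background limits dim genes, and the filter on them moved the counts.

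Counts are given as higher and lower, with the lines named as on the scanner files. With the normexp background, AEPS in the scramble line gave 1000 and 733, AEPS in the knockdown line 385 lower, knockdown in DMEM 191 and 142, knockdown under AEPS 151 and 335, the difference in response 26 and 191, limma 2522 and 2574 for AEPS and 418 and 316 for knockdown, and the share of smaller responses was 88.9%. With a 3-fold size, the same 5 comparisons gave 889 and 447, 550 and 214, 202 and 135, 123 and 280, and 10 and 92, fewer because the size asked for is larger. With no filter on dim genes, the 4 pairwise comparisons gave 2690 and 1896, 2005 and 1425, 1299 and 1048, and 1124 and 1397, since genes below background on both arrays were counted (1297, 1140, 1053 and 1088 of the calls) and no bound was asked for, and limma gave 271 and 32 for AEPS and 0 and 0 for knockdown (3043 at an unadjusted p under 0.05 of 36086 genes). With both arrays well above background, 345 genes were higher for knockdown in DMEM, since fewer genes were counted. With genes well above background on 2 or more arrays, the difference in response gave 304 and 611 and the share was 79.3%. For knockdown, limma gave 41 and 31 with the 75th percentile over measured probes, 187 and 150 with genes well above background on all 4 arrays, and 581 and 707 with an intensity trend, which gave 3622 and 3076 for AEPS. For the counts whose cause the setting's own construction does not show, the cause was not tested.

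With the value table's columns as labelled, AEPS in the scramble line gave 974 higher, AEPS in the knockdown line 1341 lower, and the difference in response 300 and 112, and the share reversed to 16.6%. Il1b became -2.47 for knockdown in DMEM, Il6 became 1.70 and Nos2 -1.17 for knockdown under AEPS, and the differences in response became 2.79 for Il1b, -1.01 for Tlr4 and 1.76 for Tnf. These follow from the exchanged columns.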

Other observations

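The tests on the value table's columns and on chromosome 9 were chosen only after those patterns were seen. Other gene groups were called for the AEPS effect in part or not at all. Oxidative stress genes rose in 4 of 14 cases and fell in 1 (5 and 2 adjusted over the list alone), with the cystine transporter gene Slc7a11 up by 4.08 and Sqstm1 by 1.51. Heat shock and unfolded protein response genes rose in 3 of 20 cases and fell in 2 (6 and 3 adjusted over the list alone), with Herpud1 up by 1.75 and Atf6 down by a log2 difference of -1.03. Of 12 genes of the small RNA machinery 0 rose and 3 fell by limma (0 and 4 adjusted over the list alone), among them Ago4 (-1.30) and Tnrc6b (-1.65). For hnRNP and splicing factors limma called 0 of 25 genes (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), for cytosolic ribosomal proteins 0 of 29 (0 and 0), for the mitochondrial respiratory chain 0 of 24 (0 and 0) and for housekeeping genes 0 of 14 (0 and 2).

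Markers of other cell types were mostly without calls. For the AEPS effect limma called 0 of 5 T, B and NK cell markers (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). Of 4 neutrophil and mast cell markers 1 rose (1 adjusted over the list alone), S100a8 by 1.04, of 6 dendritic cell markers 1 (3 adjusted over the list alone), Zbtb46 by 3.29, and of 7 fibroblast, epithelial and endothelial markers 2 (2 adjusted over the list alone), the collagen genes Col1a1 by 2.02 and Col1a2 by 0.71. Under AEPS, the 6 dendritic cell markers had a median of -0.50 on the array labelled knockdown relative to scramble (percentile 0.21, 2 above 0 and 4 below). Their median difference in response was -0.62 (1 above 0 and 5 below). For the line over both media limma called 0 of the 6. Ifnb1, the interferon beta gene, was chosen after its values were seen. Relative to each array's 75th percentile its level under AEPS was 2.60 on the array labelled scramble and 0.17 on that labelled knockdown, and in DMEM it was not well above background on either array. The receptor gene Ifnar1, chosen in the same way, lay between 1.35 and 1.55 on the 4 arrays.

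Each column of the value table stood apart from the scanner file of its own label. An exchange of the lines within each treatment is what the ranks show, with a rho of at least 0.99993 between each column and the other line's array. Another processing of the own array is argued against, since rho with it reached 0.96886 at most. Whether the scanner files or the value table carry the wrong line labels was not settled here. In the search by name, 0 gene names on the array held the targeted RNA, and probes under other names were not searched for. Either source may be the correct one.

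The block on chromosome 9 was chosen in the DMEM pair, where 6 of 254 windows passed, and was then read in the AEPS pair, which shares no array with it. All 6 windows, 2 of them higher in the block and the others lower on chromosomes 1, 3, 4 and 9, had the same direction there. Brightness or scaling of the probes is argued against by a median at percentile 100 of matched random lists, and chance placement of single genes by a familywise p of 0.0001 for the highest window over both pairs (median difference 0.36), the smallest that 10000 shuffles can give. A candidate explanation is a difference in DNA copy number between the lines, for which 86.2% of the 116 genes were higher in the AEPS pair while their AEPS effect of 0.08 lay at percentile 65.1. DNA was not measured, and a lasting regional difference in expression could give the same values.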
